A study of Mus musculus with 8 samples.

How the data were processed

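RNA from 1 mm punches of mouse medial prefrontal cortex was isolated with RNeasy columns and amplified into biotin-labelled cRNA by the Ambion MessageAmp method for hybridization to Illumina arrays, per the labels' protocols. Sample groups were taken from the sample titles, which give 4 stressed and 4 unstressed samples and number the replicates 1 to 8 without repeats, so no pairing was used.

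The authors deposited 2 tables of probe signal intensity on a linear scale, both with 45281 probes, and beside the columns of the second a deposited detection p-value for each probe and array. How the intensities were processed after scanning is not given in the sources used here. In both tables the sorted columns are nearly equal (median log2 gap 0.0011 between arrays in the value table), the form that quantile normalization leaves, although the second table is named non-normalized. The tables hold different values under the same sample names. The detection p fell or stayed level at each step of rising signal in the value table (0% rising steps), and rose at 33.4% to 36.8% of the steps in the second. The value table was therefore analysed together with the detection p-values. That choice was made from the order of the detection p-values, before any fit was compared, although the Ppm1f signals of both tables had been seen by then. The plan written before the data were examined had named background correction and quantile normalization of the second table as the main setting, with the value table as an alternative, and had provided that values found to be normalized already would not be normalized again. The second table was fitted separately and is described among the flagged results. No columns were left unmapped.

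Signals were taken to log2 without a pseudocount (lowest signal 26.9). Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, with Benjamini-Hochberg adjustment over the 20531 probes tested. Signal reached a detection p of 0.05 at a log2 value of about 6.11, so dim probes carry compressed differences. The number of arrays limits the precision: the median standard error of a log2 difference was 0.108. Each Ppm1f probe also had a two-sided exact permutation test. The plan fixed no threshold for Ppm1f; in the comparison of settings its unadjusted p at 0.05 was used, a choice made after its adjusted p had been seen.

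Probes were named through the platform annotation, updated by Entrez gene ID (0 symbols changed): 34885 probes have 1 symbol, 18 have several and 10378 are unnamed here. The Entrez gene ID of Ppm1f is 68606. No genome was used, so no coordinates are given. For gene lists each gene was represented by the tested probe with the highest mean signal. The 30 lists, fixed before the data were examined, hold 667 entries, of which 596 are named on the array and 484 were tested. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry beside it, adjusted over the lists. Fry tests whether a list's genes move on balance one way, and its mixed form whether they change in either direction.

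The genes named were Ppm1f, then 10 higher and 10 lower genes, and for each list the 2 members of smallest p and each member with p under 0.05 adjusted over the list alone. Because no gene passed, both sides were filled with the smallest unadjusted p among genes whose groups did not overlap. Unnamed probes and symbols of predicted genes were left out of these 20, as were all probes of a gene but its brightest tested one (16 probes of as small a p on the higher and 10 on the lower side). This leaves out altogether 10 and 6 genes in which only a dimmer probe met the rule. Further genes were named after their values were seen. Among list members these were Jun, Fkbp5, Cx3cr1, Hba-a1, Alas2, S100a9, Cd3e and Fech, and the heat shock members listed under other observations. The others were the genes named as met only at a dimmer probe, the tissue genes Prkcd, Zic1 and Cux2, and Hbb-bs, Nwd2 and Sorcs3.

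The fit was tested on simulated data over 20531 independently drawn probes with 200 changed probes in 20 runs, with 5.75 false calls per run on average. The list test was tried on 20 simulated lists shifted by 0.3, of which 20 were called, against 0 of 20 unshifted ones. These calls used an unadjusted camera p under 0.05, and the simulated genes were drawn independently. The 0 of 20 therefore does not measure false calls where list members move together. In the real lists the estimated correlation was 0.342 for blood and 0.928 for myelin markers. Alternatives covered normexp with offset 50, repeated quantile normalization, median scaling after neqc background correction with offset 16, cyclic loess, other probe filters, trend and robust variance, array weights (statmod 1.5.0), the mean of a gene's probes and leaving out each array. Added after seeing the data were neqc on the value table, leaving out stressed replicate 1 and unstressed replicate 6, the mean of the myelin list as a covariate, and an estimated correlation for the lists with each array left out. Slide as a block was not run because the files name no slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.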

Results

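Gene expression was measured on Illumina bead arrays in RNA from 1 mm tissue punches of the medial prefrontal cortex, taken from both hemispheres of male mice aged 10 weeks. The stressed group (4 arrays, replicates 1 to 4) came from mice immobilized for 2 h, and the tissue was examined 6 days later under basal conditions. The unstressed group (4 arrays, replicates 5 to 8) had no immobilization. Between 20012 and 21038 of the 45281 probes were detected per array (44.2% to 46.5%), and 20531 probes, standing for 11018 named genes, were tested. Probe signals correlated at r = 0.979 to 0.994 across probes within a group and at 0.975 to 0.99 between groups. The labels do not say that each array holds a separate animal, so p-values measure the spread between these samples. A second deposited table carries the same column names over different signals, and which of the tables holds the labelled arrays is not settled by the sources used here; all values below are from the table that matches the detection p-values.

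The series title names Ppm1f, a protein phosphatase that dephosphorylates Ca2+/calmodulin-dependent kinases, and the first question was whether its transcript differed 6 days after stress. In the value table both detected Ppm1f probes gave lower signal in the stressed group. Probe ILMN_1221199 had a log2 signal of 10.68 ± 0.02 (SD, n = 4) in stressed and 10.95 ± 0.14 (SD, n = 4) in unstressed samples. The log2 difference was -0.28 with a standard error of 0.0883, a change of -17.5%, and each stressed value lay below each unstressed value. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give. Any probe whose groups do not overlap has this p, and 6.92% of all probes tested were of that kind. Probe ILMN_2792756 had a log2 difference of -0.42 with a standard error of 0.125, a change of -25.2%, and its exact permutation p was 0.0571. In the limma fit the unadjusted p was 0.00978 and 0.00669, and the Benjamini-Hochberg adjusted p over all probes tested was 0.349 and 0.334, so neither probe passed at 0.05. Another probe, ILMN_2729496, was detected on 0 arrays and was not tested. Under the same labels the second table gave -0.09 (standard error 0.109, unadjusted limma p 0.43) and -0.05 (0.111, p 0.636) for these probes, and it is not settled which table holds the labelled arrays. The study chose this gene, so these values are not independent evidence of its direction.

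**Figure D1:**
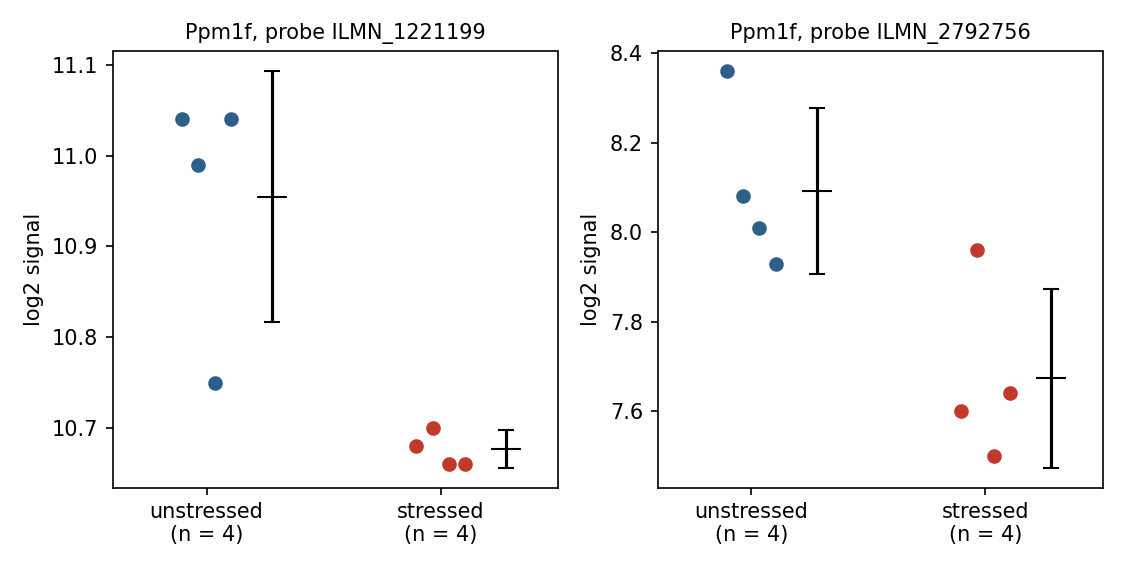
Log2 signal (vertical axis) of the 2 detected Ppm1f probes in the 4 unstressed and 4 stressed samples (points), with the group mean and SD beside them; the axes do not start at 0. Stressed values of ILMN_1221199 lie between 10.66 and 10.7, below all unstressed values, and those of ILMN_2792756 overlap by 1 sample.

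Other members of the list around Ppm1f (its homologue Ppm1e, calmodulin-dependent kinases, p21-activated kinases and their exchange factors) showed no common direction. Of 17 tested members, Ppm1f included, 11 had higher and 6 lower mean signal in stressed samples, and the median log2 difference was 0.05. Ppm1f was the only member with an unadjusted p under 0.05, and 0 passed when p was adjusted over the list alone. Arhgef7, an exchange factor that binds p21-activated kinases, had a log2 difference of 0.14 with an adjusted p of 0.559. By camera the list gave an adjusted p of 0.688.

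Genes are named here by smallest unadjusted p among annotated genes whose groups do not overlap, not by size of difference. Nptx2, a secreted pentraxin that clusters AMPA receptors at synapses, had 2.07-fold higher signal in stressed samples (log2 10.93 ± 0.26 against 9.89 ± 0.43, SD, n = 4 each). The hypoxia-inducible factor subunit Hif3a was 1.86-fold, the growth factor Hgf 1.74-fold, the innate immune protein Pglyrp1 1.67-fold and the orphan receptor Gpr22 1.61-fold higher. On the other side, Pam, the enzyme that amidates neuropeptides, had a log2 difference of -0.66, the heat shock protein Hspa4 -0.48, the mitochondrial processing peptidase subunit Pmpcb -0.46 and the G-protein regulator Rgs14 -0.46. The alpha-2C adrenergic receptor Adra2c was at -0.44, the microglial purinergic receptor P2ry12 at -0.43 and the vascular growth factor Vegfa at -0.41. The remaining genes picked by the same rule were Fam81a (0.56), Enox1 (0.53), Klhl29 (0.51), Trappc12 (0.47) and Zdhhc14 (0.42) on the higher side and Uck1 (-0.42), Ube2q1 (-0.41) and Sharpin (-0.38) on the lower side. Each gene was judged by its brightest tested probe, and 10 further genes on the higher side (among them Zfp318, Smarcd1 and Ptprr) and 6 on the lower side (among them Sox2 and Dapk1) had as small a p without overlap only at a dimmer probe. In each of the 20 genes named all 4 stressed values lay on one side of all 4 unstressed values. Wider differences without overlap lay outside this choice, with the probe of smallest p, ILMN_2486012, which has no gene name here, at 1.17, Inhba at 1.08 and the hemoglobin gene Hbb-bs at -0.84 in 1 of its 6 tested probes, the others overlapping.

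None of these differences passed the test over all probes. By limma 0 of 20531 probes had an adjusted p under 0.05 or under 0.10, and the smallest adjusted p was 0.152. An unadjusted p under 0.05 was reached by 2183 probes (10.6%), 1066 higher and 1117 lower, where 1027 are expected by chance. The groups did not overlap in 1421 probes (6.92%), against 2.86% by chance. Of the genes named above, Pglyrp1, P2ry12, Ube2q1, Uck1 and Trappc12 have other tested probes with a difference of the opposite sign, as do Oprl1, Gabrd and Ppp1r1b among the list members named below.

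**Figure D2:**
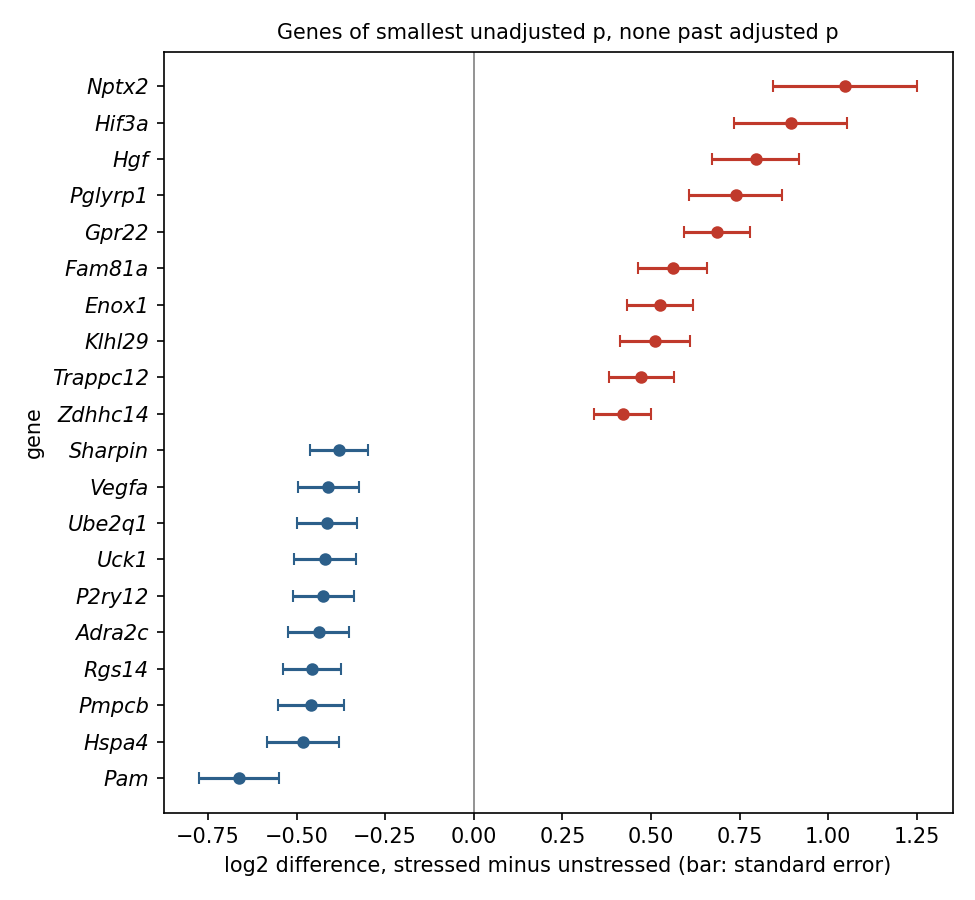
Log2 difference between stressed and unstressed samples (horizontal axis) with its standard error for the 10 higher and 10 lower genes of smallest unadjusted p among those whose groups do not overlap, each gene judged by its brightest tested probe. Differences run from -0.66 for Pam to 1.05 for Nptx2, and none passed the adjusted p over all probes.

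Neuronal activity genes went in both directions. Among 19 tested immediate early genes, Nptx2 was higher, while the transcription factor Egr4 (log2 difference -0.66) and Jun (-0.28) were lower at an unadjusted p under 0.05; Nptx2 and Egr4 passed when adjusted over the list alone, and the list as a whole did not (camera adjusted p 0.688). Of 16 tested neurotrophin and growth factor genes, Bdnf (0.45) and Vegfa (-0.41) passed over the list alone, and the list gave an adjusted p of 0.764. Inhba, the activin A subunit, had 2.11-fold higher signal in stressed samples and passed within the 9 upper-layer excitatory markers, among which Rorb had a log2 difference of 0.36 at its brightest probe and of -0.07 and -0.04 at its 2 other tested probes (list adjusted p 0.479). Syn3 (0.56) passed within 23 presynaptic genes and the active zone protein Bsn (0.31) did not (list adjusted p 0.479). Bsn was near background, detected on 4 stressed and 3 unstressed arrays. Adra2c passed within 8 monoamine genes, where the serotonin receptor Htr1a had a difference of 0.30 that ran from 0.147 to 0.44 with single arrays left out (list adjusted p 0.688). Mgll, the enzyme that degrades 2-arachidonoylglycerol, had a difference of -0.33 and passed within 8 endocannabinoid genes, beside Abhd6 at -0.24, which did not (list adjusted p 0.628).

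Stress hormone targets showed no common direction. Of 21 tested glucocorticoid-responsive genes 4 were higher and 3 lower at an unadjusted p under 0.05, with the perilipin Plin4, detected on 4 stressed and 1 unstressed arrays, higher in stressed samples and Per1 at -0.49; 0 passed over the list alone, and the list gave a camera adjusted p of 0.628. Fkbp5, the receptor co-chaperone, had a difference of 0.30 with an adjusted p of 0.509. Among 9 genes of the stress axis Hsd11b1, which regenerates corticosterone, had a difference of -0.31 (-0.187 without unstressed replicate 6), and Crhr2 was near background, detected on 1 stressed and 4 unstressed arrays (list adjusted p 0.688).

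Clock genes had lower signal in stressed samples in 13 of 15 tested members, and the list just missed the threshold (camera adjusted p 0.0521, and adjusted p 0.945 with an estimated correlation). Bhlhe40 (-0.61), Per1 (-0.49) and Tef (-0.45) passed when adjusted over the list alone. Genes of the heat shock and unfolded protein response had higher signal in 18 of 24 tested members, also just short of the threshold (camera adjusted p 0.0521, and adjusted p 0.843 with an estimated correlation). The estimated correlation of the heat shock list was 0.007, below the preset 0.01, and the camera p with it was 0.0281 before adjustment over the lists. Members moving together therefore do not account for the higher p of this list. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, had a difference of 0.47 and passed over the list alone, while the cytosolic chaperone Hsp90aa1 had a difference of -0.35 and did not, with its other probe of opposite sign. Both lists passed without stressed replicate 2 (adjusted p 0.0206 and 0.0214) or unstressed replicate 6 (0.00396 and 0.0447), the clock list also without stressed replicate 1 (0.0493) or unstressed replicate 5 (0.0472), and the heat shock list without unstressed replicate 7 (0.0189). With an estimated correlation the smallest adjusted p of any list called without 1 array was 0.574.

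Blood cell markers were lower in stressed samples as a list only by camera at the preset correlation. All 8 tested members had lower mean signal in stressed samples, with a median log2 difference of -0.48 and a camera adjusted p of 0.00353. The adjusted p was 0.936 with an estimated correlation and 0.426 by fry. The median and the count of 8 rest partly on genes near background, which lies at a log2 signal of about 6.11. Mean signals in stressed and unstressed samples were 5.92 and 6.4 for S100a9, 6.1 and 6.29 for Cd3e and 6.4 and 6.47 for Fech. Ube2l6 (6.17 and 6.51) was detected on 3 stressed and 4 unstressed arrays. Hbb-bt (13.02 and 13.71) and Hba-a1 (13.04 and 13.71) were bright, but their groups overlapped. The hemoglobin genes Hbb-bt and Hba-a1 had differences of -0.69 and -0.67, and Ube2l6, a ubiquitin-like conjugation enzyme also made outside blood, of -0.34; 0 members passed over the list alone. Alas2, an enzyme of heme synthesis in red cells, was highest in unstressed replicate 5 at a log2 signal of 9.3, against 6.84 to 8.04 in the other arrays. Blood was the 1 list of 30 past the threshold; leaving out stressed replicate 1 or unstressed replicate 7 raised the count to 6, unstressed replicate 6 to 4, stressed replicate 2 to 3 and unstressed replicate 5 to 2. With an estimated correlation or by fry the count was 0.

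Other cell type markers were mostly below the threshold. Leaving out 1 array moved several of these lists either way. Without stressed replicate 1 they were lower in stressed samples, with an adjusted p of 0.000758 for endothelial, 0.0114 for mural and meningeal and 0.0129 for astrocyte markers. Without unstressed replicate 7 it was 0.0373, 0.0189 and 0.0189 for these and 0.0189 for microglial markers, and without unstressed replicate 6 it was 0.0447 for endothelial markers. With an estimated correlation 0 of these calls remained. Without stressed replicate 3 the mean difference of astrocyte markers turned from -0.052 to 0.03 and that of mural and meningeal markers from -0.107 to 0.046, and without unstressed replicate 8 they were -0.004 and -0.019. Of 17 microglial markers 11 had lower and 6 higher mean signal in stressed samples, and the list gave an adjusted p of 0.268. P2ry12 (-0.43, with its other probe of opposite sign) and Gpr34 (-0.33) passed over the list alone. Cx3cr1 was higher, at 0.20 with an unadjusted limma p of 0.0419, and did not pass over the list alone. The endothelial tight junction gene Cldn5 had a difference of -0.44 and Itm2a of -0.57 among 15 endothelial markers (list adjusted p 0.13). Mural and meningeal markers included Ptgds (-0.44, and -0.26 without unstressed replicate 8) and Pdgfrb (-0.21), with a list adjusted p of 0.479. Among choroid plexus and ependymal markers Ttr, a transport protein of that tissue, ranged from 6.32 to 11.57 across arrays and had a difference of -1.48 with a standard error of 0.802, from -0.833 without unstressed replicate 7 to -2.006 without unstressed replicate 8, and Foxj1 had one of -0.19 (list adjusted p 0.268). Glul (-0.29) and Acsbg1 (-0.32) led the astrocyte markers (adjusted p 0.507), and Cacng4 (0.27) and Pdgfra (0.18) the oligodendrocyte precursor markers (adjusted p 0.896). Pvalb had a difference of -0.48 and Sox6 of 0.24 among 19 interneuron markers (adjusted p 0.861). Deep-layer excitatory markers (Crym 0.17, Tle4 -0.11) gave an adjusted p of 0.914, striatal markers (Pde1b 0.16, Ppp1r1b -0.28) one of 0.896 and olfactory bulb markers (Omp -0.18, Slc17a6 -0.35) one of 0.688. Single arrays carried some of these values: Pde1b was at 0.03 without stressed replicate 1, and without unstressed replicate 6 Slc17a6 was at -0.07 and Ppp1r1b at 0.0037. With single arrays left out Crym ran from 0.079 to 0.289, Tle4 from -0.029 to -0.237, Sox6 from 0.156 to 0.324, Pdgfra from 0.116 to 0.25 and Omp from -0.087 to -0.22.

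Myelin and its neighbours varied between punches within both groups. The 15 oligodendrocyte and myelin markers had a median difference of -0.22 (adjusted p 0.479), with Opalin at -0.47 and Mal at -0.47 and standard errors of 0.372 and 0.421. Without stressed replicate 1 the list was lower in stressed samples with an adjusted p of 7.12e-05, and an adjusted p of 0.889 with an estimated correlation. Without unstressed replicate 6 its mean difference turned from -0.207 to 0.1, and Opalin and Mal were at -0.11 and -0.12. No other single array turned its sign. With both of these arrays left out the list was lower in stressed samples, with a camera adjusted p of 0.00189 at the preset correlation. The estimated correlation was not run for that setting. The list's centred mean was 0.926 in stressed replicate 1 and 1.02 in unstressed replicate 6, and -0.59 to 0.036 in the other arrays. The same pair of arrays had log2 signals of 10.1 and 10.3 for Prkcd and 11.86 and 11.63 for Zic1, both abundant in forebrain regions beneath the cortex, where the other arrays had 7.37 to 7.69 and 8.81 to 9.7. Cux2, an upper-layer cortical gene, was at 7.85 and 8.04 there and at 9.15 to 9.8 elsewhere. Without these 2 arrays 1 probe passed the adjusted p, that of Nwd2, with a log2 difference of 1.11 and an adjusted p of 0.0306. A split of all 8 arrays that mixed the groups, with these 2 arrays on one side, had 2 probes past it.

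**Figure D3:**
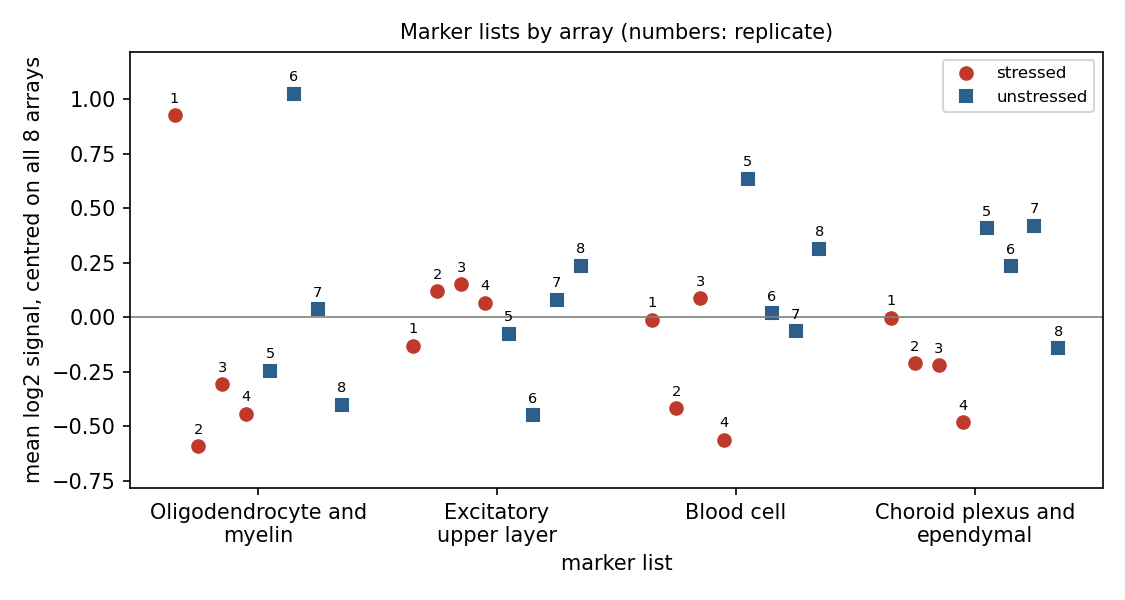
Mean log2 signal of 4 marker lists, centred on all 8 arrays (vertical axis), for each array; circles are stressed and squares unstressed samples, numbered by replicate. Stressed replicate 1 and unstressed replicate 6 have the highest myelin values, 0.926 and 1.02, and unstressed replicate 5 has the highest blood value, 0.634.

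The remaining lists gave no call over their members or as a whole. Glutamate receptor and scaffold genes had an adjusted p of 0.454 (Grin2b 0.21, Grm4 0.23), GABA receptors of 0.764 (Gabrb2 -0.34, Gabrd -0.21), and neuropeptide and opioid genes of 0.896 (Oprl1 -0.14, Npy1r 0.32). With single arrays left out Grm4 ran from 0.106 to 0.321, Gabrd from -0.093 to -0.38, Oprl1 from -0.084 to -0.19 and Npy1r from 0.182 to 0.512. Inflammation and cytokine genes had one of 0.688, with the chemokine Cxcl12 at -0.40 and Vcam1 at 0.30. Oxidative phosphorylation genes had one of 0.764 (Sdhd -0.41, Atp5e -0.27), cytosolic ribosomal proteins of 0.896 (Rplp2 0.30, Rps25 -0.32) and chromatin enzymes of 0.59 (Kdm6b -0.27, Hdac2 -0.22). Over all 30 lists 14 members passed when adjusted over their list alone and 0 when adjusted over all probes. On simulated arrays with the same spread, limma recovered 39.9% of probes changed by 0.5 on the log2 scale and 88.4% of those changed by 1.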

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

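The tests of the second table, of other groupings of the arrays and of time of day were chosen after the results they measure, or part of them, had been seen; the tests with the myelin list as a covariate were set down before their results were seen.

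The signal columns of the second deposited table share sample names with the value table but not its signals. No column of one table matched any column of the other: after probe means were removed the highest correlation over all pairs was 0.37, which argues against the same columns in another order. The detection p beside the second table's columns rose with signal at no fewer than 33.4% of steps, against 0% in the value table, as it would if those signals came from other arrays. Alas2 shows the mismatch in a single gene, with a log2 signal of 12.49 in column 3 of the second table and 7.55 in column 3 of the value table. Each detection p column matched best the value table's column of the same sample, so these share an order of samples. The 2 tables have nearly the same distribution of signal, with a median log2 gap of 7.6e-05 between their mean sorted columns. Normalization to a common target would leave this form, but it does not tell which arrays the second table holds. Which arrays the second table's signals come from, and which table carries the group labels correctly, stays open, and no biological explanation was tested.

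Fitted by limma under the same labels, the second table gave 0 of 20531 probes past an adjusted p of 0.05 (smallest 0.981) and 567 with an unadjusted p under 0.05 (2.76%), fewer than the 1027 expected by chance. Its log2 differences correlated at -0.16 across probes with those of the value table. Ppm1f had log2 differences of -0.09 (standard error 0.109, p 0.43) at ILMN_1221199 and -0.05 (standard error 0.111, p 0.636) at ILMN_2792756. Neither difference exceeded its standard error.

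The excess of probes with a small unadjusted p is the second pattern. In 2 of the 35 splits of the 8 arrays into 4 and 4, the real one included, as many probes had an unadjusted p under 0.05. The real split gave 2183 and the highest other 2255, so chance cannot be excluded. Both that split and the next (2073) put stressed replicate 1 and unstressed replicate 6, the arrays of highest myelin signal, on one side. Of splits that part these arrays, as the real one does, the highest other gave 1063. This was looked at after the counts were seen, and chance stays open. In the split with 2073, 2 probes passed an adjusted p of 0.05 by limma, against 0 in the real one. With the myelin list mean as a covariate the number was 2688. That list's mean was -0.103 (SD 0.696) in stressed and 0.103 (SD 0.64) in unstressed samples, so the covariate was nearly unrelated to the grouping. It could remove little of a group difference, and this test cannot decide on unequal myelinated tissue. The lower Ppm1f signal kept 100.8% or more of its size in both probes with that covariate, with the same limit. Only the myelin list was run as a covariate, so unequal content of other tissue, such as blood, was not tested. An effect of stress stays among the open explanations, beside chance and unequal tissue in the punches.

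Lower Bhlhe40, Per1 and Tef are the third pattern. For tissue collected at different times of day, the prediction was lower signal in other genes driven by the clock and higher Arntl and Npas2. It assumed that these output genes shift together, which was not tested. The 6 other output genes tested had a median log2 difference of -0.076, against -0.489 for the 3 genes, and 5 of them were lower. That median less 2 standard errors, -0.242, clears the bound of -0.245 barely, and with the myelin covariate it does not (-0.302 against -0.271). Arntl (-0.23, standard error 0.105) and Npas2 (-0.04, standard error 0.136) did not go the other way, but Npas2 lay within its standard error. By the bounds as first set these values spoke against time of day, and the bounds were tightened after the values were seen. The 3 genes were also picked for small p from this list, which favours a smaller median in the rest. The test is too weak to decide, and time of day stays open. With the myelin covariate, which was nearly unrelated to the grouping, the 3 genes kept 110.6% of their median difference. That does not decide on unequal myelinated tissue, and a response to stress stays open too.

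Single arrays far from the other 3 of their group were found in 14 of 214 groups of 4 (6.5%), close to the 5% that chance gives. The figure given for each is the gap to the nearest array divided by the group's range. In the stressed group these were Zdhhc14 in replicate 4 (0.95), Mal (0.844) and Acsbg1 (0.924) in replicate 1, Ttr in replicate 4 (0.83), Vcam1 in replicate 3 (0.832) and the olfactory bulb list in replicate 1 (0.838). In the unstressed group they were Rgs14 (0.909), Tle4 (0.884) and the heat shock and unfolded protein list (0.887) in replicate 8, Plin4 in replicate 6 (0.846), Itm2a in replicate 5 (0.889), Kdm6b in replicate 7 (0.872), the glutamate receptor list in replicate 5 (0.888) and the astrocyte list in replicate 7 (0.837).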

How the results depend on the processing

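The settings without the 2 arrays of highest myelin signal, with the myelin list as a covariate and with neqc were chosen after seeing the data. Both Ppm1f probes stayed lower in stressed samples with an unadjusted p under 0.05 in all settings run on the value table, from -0.25 to -0.35 for ILMN_1221199 and from -0.33 to -0.51 for ILMN_2792756 when single arrays were left out. No setting brought a named gene past the adjusted p, and of 1436 values of named genes under other settings 1434 kept their direction. Tle4 turned to 0.015 without the 2 arrays of highest myelin signal, and the log2 difference of Ppp1r1b to 0.0037 without unstressed replicate 6 (range -0.598 to 0.0037 over single arrays left out); the cause was not tested. Leaving out 1 array moved 18 of the 76 named genes by over 1.5 times, 0 of them Ppm1f or among the 10 higher and 10 lower. The 10 higher and 10 lower genes were picked for small p without overlap, so their stability was largely fixed by that choice. The count of probes past the adjusted p was 0 in each setting but the one without the 2 arrays, where it was 1. Probes with an unadjusted p under 0.05 numbered 3770 with no filter, where 45281 probes were tested, 3110 (15.1%) with array weights on the same 20531 probes, the highest share of any setting, and 1467 to 2407 with single arrays left out, the lowest without stressed replicate 2.

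The number of lists past the threshold, 1 as reported, depended on most settings. It was 4 with no filter, 4 with the mean of a gene's probes, 4 without the 2 arrays, 3 with trend and robust variance, 3 with the myelin covariate and 2 with array weights. It was 0 with detection on all 8 arrays, where the blood list was too short to test, 0 with an estimated correlation and 0 by fry. With single arrays left out it ran from 1 to 6, with 6 without stressed replicate 1 or unstressed replicate 7, 4 without unstressed replicate 6, 3 without stressed replicate 2 and 2 without unstressed replicate 5. The lists gained were clock, heat shock, endothelial, mural, microglial, astrocyte and oligodendrocyte lists; the cause was not tested. Repeating quantile normalization moved almost nothing, as the values were normalized already. Slide as a block was not run. No paired analysis was possible because the groups share no replicate numbers.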

Other observations

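The heat shock and unfolded protein list had 7 members higher and 2 lower in stressed samples at an unadjusted limma p under 0.05, and 15 of 24 without; none passed over all probes. Besides Sdf2l1 and Hsp90aa1 these were Calr (log2 difference 0.49), Hspb1 (0.35), Pdia4 (0.28), Pdia3 (0.27), Hsp90b1 (0.26), Hspa5 (0.26) and the transcription factor Atf4 (-0.23), named after their values were seen. Other endoplasmic reticulum members had smaller differences, with Herpud1 at 0.13, Creld2 at 0.12, Pdia6 at 0.05 and Dnajb9 at -0.05. The list's mean lay between 0.016 and 0.073 in the 4 stressed arrays and between -0.086 and -0.033 in the 4 unstressed arrays. It was the 1 list of 30 whose groups did not overlap, where 0.86 is expected by chance, so this separation is no more than chance gives. By fry's mixed test, which asks for change in either direction, this list (adjusted p 0.000285), the microglial list (0.00474) and the glucocorticoid-responsive list (0.0139) passed. None of these passed fry's test for one direction (0.144, 0.833 and 0.926), or camera with an estimated correlation (0.843, 0.945 and 0.945).

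Higher Nptx2, Inhba and Bdnf raised the hypothesis of a wider rise of late activity-regulated neuronal genes. The test was run after part of its result had been seen, since Vgf, one of its genes, was known to be higher. The other 15 genes tested, of 17 listed, had a median log2 difference of 0.032 (0.028 without Vgf), and a one-sided exact permutation test gave p = 0.3. Sorcs3 had a difference of 0.53, and 9 of the 15 genes were higher. The test left the hypothesis undecided, since the members went both ways.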
